A study of Mus musculus with 2 samples.

How the data were processed

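Chromatin accessibility was measured by single-nucleus ATAC-seq (10x Genomics) in 2 samples, 1 wild-type and 1 homozygous mutant, with 1 library per group. Per the labels' protocols, the mice were male littermates of 8 to 10 weeks, liver cells other than hepatocytes were enriched with F4/80 beads, and 8000 nuclei at 25000 read pairs each were aimed at, sequenced for 50 cycles. Cell Ranger ATAC 1.2.0, Cell Ranger, R 3.6.1, Seurat and Signac 0.2.4 are named in the submitters' processing notes, with genome build GRCm38.p5. The table the authors deposited holds both libraries and gives counts, not normalized, of read pairs per unique fragment. In genes and bins each unique fragment was counted once. Read pairs were used for sequencing depth and for thinning library 2 to the depth of library 1. The steps before deposit are known only from the tools just named. A deposited per-barcode table gave totals of fragments, fragments in peaks, fragments near transcription start sites, blacklisted fragments and duplicates, with the authors' cell calls, whose threshold is not given in the sources used here. Neither the labels nor the files used here pair a barcode suffix with a genotype, so every value belongs to library 1 or library 2. The reference was a gene table of GRCm38.p6, a patch release that shares the coordinates of the primary chromosomes with the build of the files. In a check on 13962 genes, the annotated gene end with more fragments held a median of 168.5 fragments, the other end 11 and the middle of the gene 11. The fuller end exceeds the other end by definition, so only the value of the middle bears on the coordinates.

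Cells were the authors' calls with at least 1000 fragments in peaks, at least 15% of fragments in peaks and at most 5% in blacklisted regions, which left 609 of 637 and 562 of 575. Fragments were counted in 5 kb bins, of which the 337808 seen in at least 10 cells were kept, weighted by TF-IDF and reduced to 30 components by truncated SVD with scikit-learn 1.9.0. The first component was left out, a graph of 20 neighbours was built on the other 29, and Leiden clustering at resolution 0.5 (leidenalg 0.10.2, igraph 0.11.9) gave 10 clusters. A cluster was named after a marker list when its score reached 0.25, led the next list by 0.2 and rested on 3 markers each found in 10% of the cells, and the 14 marker lists held 126 genes, all 126 matched. Cells marked as doublets were kept. A score against simulated pairs (scrublet in scanpy 1.11.5) marked 16 and 13 cells, an overlap rule like AMULET at q 0.01 marked 68 and 85, and both marked 8 and 6.

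Fragments that overlapped a gene body with 2 kb on both sides were summed over the cells of a class in each library, for 21887 protein-coding genes. The plan was for 2 kb upstream alone, but the gene table used here gives no strand. Levels are fragments of a gene in CPM, scaled by all fragments of the class, with exact Poisson intervals. Log2 ratios carry exact conditional binomial intervals, with 0.5 added to both counts for the point value, for genes with at least 50 fragments. The median of each of the 9 gene lists (112 of 113 symbols matched, Mx1 not matched, none a marker) was set against 10000 random lists of the same size drawn from 20 bins of level, and counts of higher and lower genes use the interval relative to the median gene. Classes with 100 cells in each library were compared, which left Kupffer-like and endothelial-like cells. No test across samples was possible with 1 library per group, and no p-value is given. Named genes were chosen before the data were examined by a rule of size, namely the members of each list with the largest and smallest ratios, the 10 highest and 10 lowest genes of the Kupffer-like class with at least 100 fragments, and the 5 highest and 5 lowest of the endothelial-like class, with 1 gene per group of overlapping windows. Results of 2 single genes, 1 of them picked by this rule, are not reported here. Other genes named, such as Hmox1 bins, Slc40a1 and Marco, were picked as list members or after their values were seen.

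A pile-up was a 20 kb bin with at least 10 fragments of a cell and at least 10 times the number expected at its depth from the other cells of its cluster, a definition chosen after seeing the data, and masking left out the fragments in such bins. Alternatives planned beforehand were no cell filter, a minimum of 3000 fragments in peaks, 20 kb bins, Leiden resolution 1, both doublet rules, scaling by fragments near transcription start sites, counting insertions, no minimum per gene and cells thinned to 5000 fragments. Alternatives chosen after seeing the data were 1 kb on each side of the fuller gene end, masked pile-ups, cells with at least 50% of fragments in peaks, gene bodies without flanks and random lists matched on window length as well. Motif accessibility was planned and not run, since no genome sequence was used here, and windows at transcription start sites were replaced by fuller gene ends, since strand was not used here.

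The counting procedure was tested on simulated data, with the Kupffer-like pools of 16056 genes. Apart from the changed genes, both pools were drawn as Poisson counts around 1 shared level per gene. The intervals assume the same, so the rates below do not cover pile-ups or differences between cells. Intervals excluded no change for 74% of 50 genes changed 1.5 times, 98% of those changed 2 times, 95.9% of 49 genes changed 0.5 times and 4.25% of unchanged genes, and 4.5% of 200 lists of unchanged genes fell outside the central 95%. The pools held 5744610 and 4709546 fragments of Kupffer-like cells and 1463306 and 1702205 of endothelial-like cells in libraries 1 and 2. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, anndata 0.12.19 and matplotlib 3.10.9 were used, with random seed 1.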

Results

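Open chromatin was profiled in single nuclei from mouse liver by droplet-based ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA. The nuclei came from non-parenchymal cells that had been enriched with beads against F4/80, a surface protein of tissue macrophages. There were 2 libraries, 1 of the wild type and 1 of homozygous mutant littermates with fragile red blood cells. The series asks how the uptake of red blood cells by liver macrophages relates to their inflammatory state. The barcodes carry the suffix 1 or 2, and the labels and files used here do not tie either suffix to a genotype. Values are therefore given for library 1 and library 2, no genotype is compared, and there are no replicates, so no test was run. All intervals are 95% intervals that cover counting error only.

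Library 1 held 11401694 fragments from 116789 barcodes, and library 2 held 21656110 fragments from 180316 barcodes. The deposited calls marked 637 barcodes of library 1 and 575 of library 2 as cells, with medians of 13220 and 13186 fragments per cell. These cells held 83.2% of the fragments in library 1 and 56.2% in library 2. The median share of a cell's fragments inside the peaks of the deposited per-barcode table was 72.1% in library 1 and 53.7% in library 2. The cells of library 2 also carried local pile-ups, defined as stretches of 20 kb where a single cell had 10 or more fragments and at least 10 times the number expected at its depth from the other cells of its cluster. Pile-ups held 12% of the fragments of filtered cells in library 2, at 129 per cell, and 0.647% in library 1, at 7.39 per cell. Between-library values of single genes were therefore also computed with pile-ups masked.

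**Figure D1:**
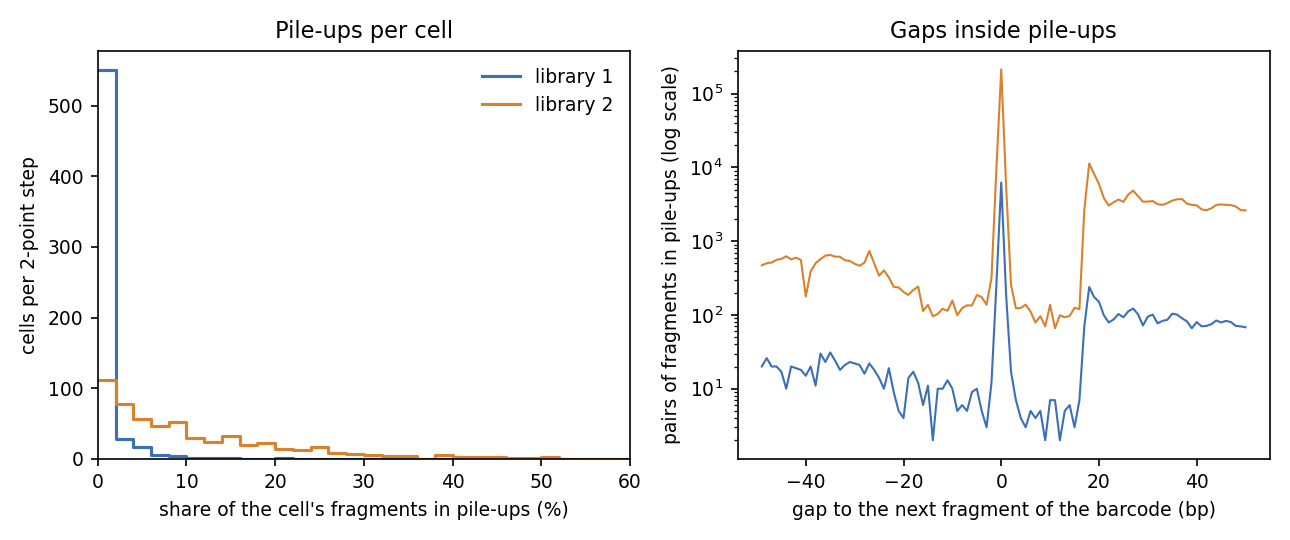
The left panel shows the number of cells per step of 2 percentage points in the share of a cell's fragments that lay in pile-ups, for library 1 (blue) and library 2 (orange), with medians of 0 and 7.57%. The right panel shows, on a log scale, the number of neighbouring fragment pairs inside pile-ups by the gap between them in bp, with negative gaps for overlaps, and both libraries peak at a gap of 0.

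Most filtered cells were Kupffer-like, endothelial-like or stellate or fibroblast-like. Kupffer-like cells, named from markers of resident liver macrophages such as Clec4f, Vsig4 and Timd4, made up 53.7% (327 of 609 filtered cells; 49.6 to 57.7%) of library 1 and 45.2% (254 of 562; 41.0 to 49.4%) of library 2. Liver endothelial-like cells made up 16.6% (13.7 to 19.8%) and 19.2% (16.0 to 22.7%). Stellate or fibroblast-like cells made up 11.2% (8.78 to 13.9%) of library 1 and 4.63% (3.04 to 6.71%) of library 2. Hepatocyte-like cells numbered 25 in library 1, or 4.11% (2.67 to 6.0%), and 1 in library 2, or 0.178% (0.0045 to 0.987%). Intervals are exact Clopper-Pearson intervals, and the shares describe what passed the F4/80 enrichment, not the liver.

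Kupffer-like cells of the 2 libraries fell into different clusters. Cluster 1 held 246 of the Kupffer-like cells of library 2 and 3 of library 1. Clusters 3, 5 and 9 held 132, 106 and 86 Kupffer-like cells of library 1, against 0, 7 and 1 of library 2. The absence from cluster 3 (0 of 562 cells) allows a share of library 2 of up to 0.534% when taken as 3 cells, and of up to 0.654% by the exact interval. Endothelial-like cells were split in the same way, with 99 cells of library 1 and 10 of library 2 in cluster 6, and 2 and 98 in cluster 7. Stellate or fibroblast-like cells of both libraries shared cluster 8. With 1 library per genotype, a cluster mostly of 1 library is not told apart from that library's own features. The leading genes of cluster 1 were protocadherin genes such as Pcdha12, and with pile-ups masked they were led by Marco and included Hmox1 and Spic, while cluster 3 was led by Vsig4 and C1qb, and cluster 7 by Elavl2 and Fgf23. The unnamed clusters 2 and 4 made up 14.4% of library 1 and 30.8% of library 2, shares that ranged from 8.87% to 22.9% and from 12.4% to 35.8% in other settings. Cluster 2 scored highest for B-cell markers, closely followed by monocyte markers, and cluster 4 for erythroid markers, closely followed by basophil markers. The median share in peaks of the cells in cluster 4 was 52.0% in library 1 and 29.4% in library 2. Without the cells that had many positions covered by more than 2 fragments, the hepatocyte-like share of library 2 came to 16.8% and its unnamed share to 12.4%. The cluster then named hepatocyte-like had leading genes of the unnamed cluster 4, such as Ofcc1, Sema3c and Ano1, so the name is not firm, and the cause of the change was not tested.

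**Figure D2:**
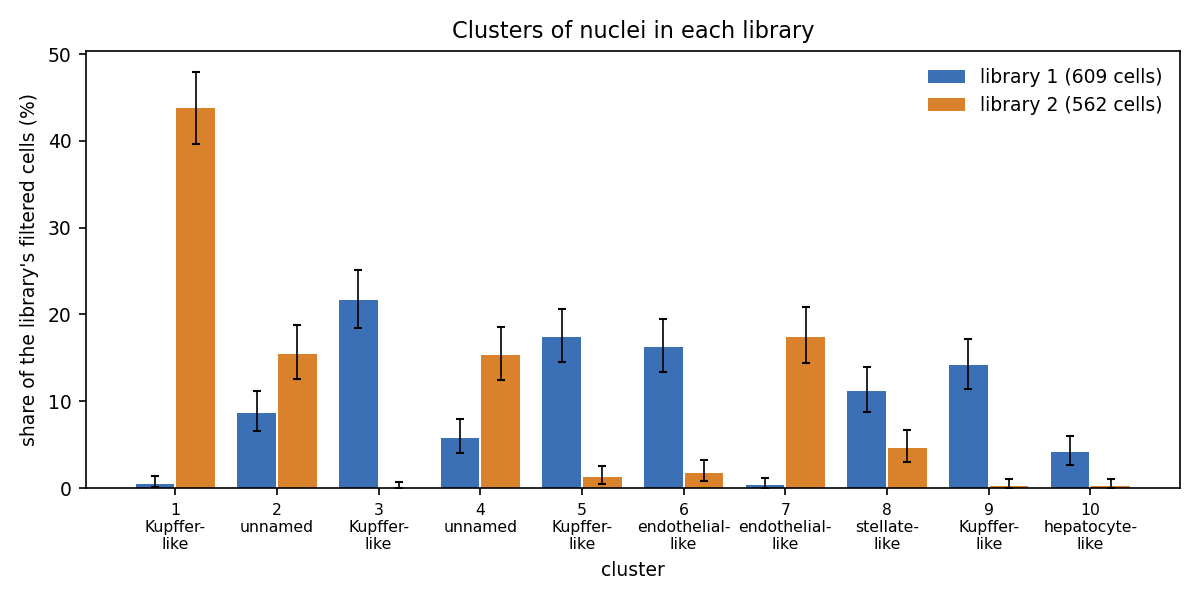
Bars show each cluster's share of the filtered cells of library 1 (609 cells, blue) and library 2 (562 cells, orange) in percent, with exact 95% binomial intervals as error bars. Cluster 1 took 43.8% of library 2 and 0.493% of library 1, while clusters 3, 5 and 9 lay mostly in library 1.

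The first comparison asks which of the fixed gene groups were more accessible in macrophages than in endothelial cells of the same library, where handling was shared. Kupffer-like chromatin was more open at heme and iron genes, inflammatory genes and MHC class II genes in both libraries. Cd163, the receptor for hemoglobin bound to haptoglobin, had log2 ratios of Kupffer-like over endothelial-like cells of 4.10 (3.19 to 5.40) in library 1 and 2.24 (1.44 to 3.27) in library 2. The iron exporter gene Slc40a1 had ratios of 1.72 (1.33 to 2.17) and 2.20 (1.70 to 2.78). Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, had ratios of 0.89 (0.47 to 1.37) and 1.67 (1.32 to 2.06). Log2 ratios of genes are relative to the median gene of the comparison, which lay at -0.02 in library 1 and -0.11 in library 2, and a gene is called higher or lower where its interval excludes that median.

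In the heme and iron handling list, 11 of 16 genes were higher in Kupffer-like cells, 2 were lower and 3 were neither in each library. The list median exceeded that of random lists matched on level by 0.55 in library 1 and 0.85 in library 2, at percentiles 99.8 and 99.99 of 10000 random lists. Over all settings the excess ranged from 0.21 to 0.72 in library 1 and from 0.29 to 0.92 in library 2. The lowest percentiles were 94.7 and 98.4, so the library 1 value did not stay outside the central 95% throughout. In the inflammatory response list, 11 of 16 genes were higher, 0 lower and 5 neither in library 1, and 12 were higher, 1 lower and 3 neither in library 2, with excesses of 1.62 and 1.1. The chemokine gene Ccl4 reached 3.6 (2.78 to 4.74) and 3.07 (2.19 to 4.29), and the inflammasome gene Nlrp3 1.84 (1.39 to 2.38) and 1.73 (1.19 to 2.37). The window of Ccl4 overlaps that of Ccl3, which was also counted as higher, so their ratios share fragments. Cxcl10 was the lower gene, at -1.02 (-1.61 to -0.41) in library 2. In the MHC class II and co-stimulation list, 9 of 10 genes were higher and 1 was neither in library 1, and 8 of 9 were higher and 1 was neither in library 2, with excesses of 1.94 and 1.27. Cd86, a co-stimulatory ligand for T cells, reached 3.78 (3.18 to 4.53) and 3.0 (2.49 to 3.62), and Cd74, the invariant chain of MHC class II, 2.98 (2.42 to 3.66) and 1.91 (1.30 to 2.67).

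In the main setting the other lists had smaller excesses, and only the engulfment list of library 1, at percentile 98.4, and the NRF2 list of library 2, also at 98.4, lay outside the central 95% of random lists. Both calls depended on the setting, with lowest percentiles of 42.6 and 93.25, and other lists came outside in some settings. Of the genes in the engulfment and scavenger receptor list, 7 of 12 were higher, 4 lower and 1 neither in library 1. In library 2, 6 were higher, 3 lower and 3 neither, and the excesses were 0.53 and 0.48. Lrp1, which clears hemopexin with bound heme, was higher at 3.09 (2.79 to 3.42) and 2.93 (2.62 to 3.29), and Stab1, a scavenger receptor shared with sinusoidal endothelium, was lower at -0.65 (-0.90 to -0.40) and -1.35 (-1.71 to -1.0). Of the NRF2 antioxidant targets, 6 of 13 were higher, 1 lower and 6 neither in library 1, and 7 of 14 were higher, 2 lower and 5 neither in library 2, with excesses of 0.39 and 0.48. Gsr, glutathione reductase, was higher at 1.58 (1.25 to 1.94) and 1.53 (1.2 to 1.89), while Nqo1 was lower at -1.62 (-2.16 to -1.07) and -1.11 (-1.59 to -0.62). Of the anti-inflammatory and alternative activation genes, 6 of 11 were higher, 4 lower and 1 neither in library 1, and 5 of 10 were higher, 3 lower and 2 neither in library 2, with excesses of 0.42 and 0.41. Il1rn, which encodes the interleukin 1 receptor antagonist, was higher at 4.18 (2.62 to 7.55) and 2.36 (1.2 to 4.15), and the interleukin 4 receptor gene Il4ra was lower at -0.70 (-0.90 to -0.50) and -1.14 (-1.36 to -0.91).

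The macrophage identity factors had excesses of 0.25 and 0.27, with Spi1, the gene of the myeloid factor PU.1, at 1.94 (1.59 to 2.33) and 1.77 (1.35 to 2.24). In that list 6, 1 and 5 of 12 genes were higher, lower and neither in library 1, and 5, 4 and 3 in library 2. Over all settings its percentile ranged from 81.48 to 99.89 in library 1 and from 61.45 to 99.93 in library 2. The LXR and lipid handling list had excesses of 0.14 and 0.17, with 4, 1 and 4 of 9 genes higher, lower and neither in library 1 and 3, 1 and 5 in library 2. The cholesterol exporter gene Abca1 was higher at 1.64 (1.43 to 1.86) and 0.94 (0.77 to 1.12), and Abcg1 was lower at -0.60 (-0.79 to -0.40) and -0.49 (-0.74 to -0.23). The interferon response list had an excess of 0.17 in library 1, with 1 of 9 genes higher, 0 lower and 8 neither, and of -0.47 in library 2, with 2 of 7 higher, 4 lower and 1 neither. Irf7, an inducer of interferon genes, was higher at 0.72 (0.15 to 1.38) and 1.05 (0.45 to 1.75). The library 2 interferon value turned to 0.17, and the library 1 engulfment value to -0.03, when windows of 1 kb on each side of a gene's fuller end were counted. Of the Kupffer markers, which named the classes, 9 of 9 were higher in library 1, and 7 were higher and 2 neither in library 2, while 12 of 12 endothelial markers were lower in each.

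**Figure D3:**
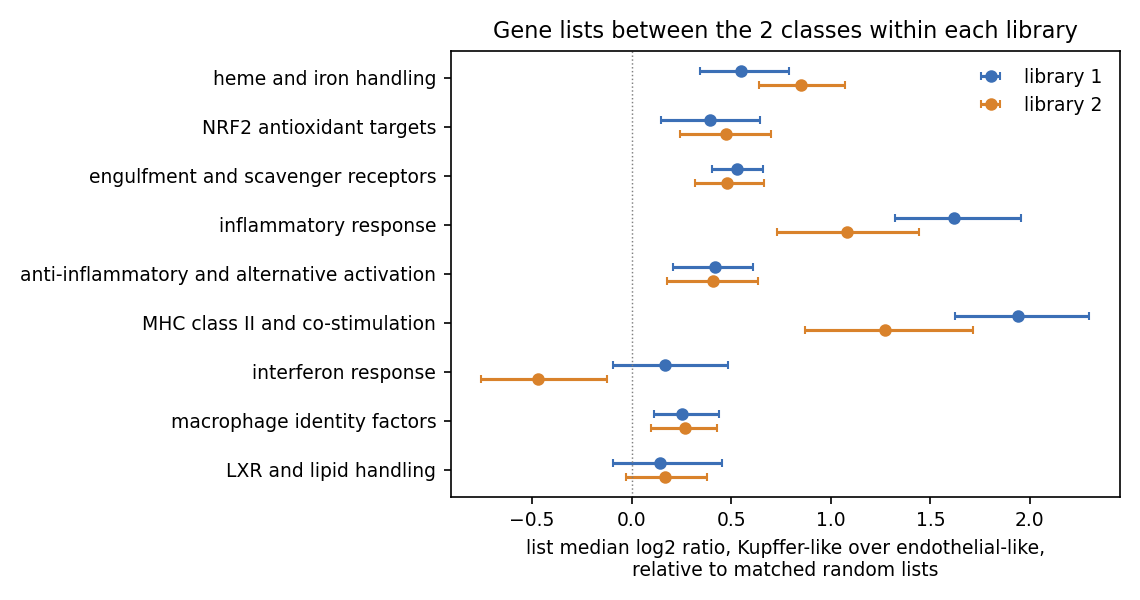
Points show the median log2 ratio of each gene list, Kupffer-like over endothelial-like cells, relative to matched random lists in library 1 (blue) and library 2 (orange), with 95% counting intervals as error bars. The inflammatory and MHC class II lists stand highest in both libraries, at 1.62 and 1.94 in library 1.

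The next comparison sets the Kupffer-like cells of library 2 against those of library 1, which asks how the macrophages of the 2 libraries differed, with no genotype assigned to either. Values come mostly from cluster 1 for library 2, which scored lower for Kupffer markers, and from clusters 3, 5 and 9 for library 1. Chromatin at Hmox1 and the ferritin heavy chain gene Fth1 was more open in library 2, while chromatin at the MHC class II genes was less open. Hmox1 held 348 fragments, or 60.6 CPM (fragments scaled by the total of the class; 54.4 to 67.3), in library 1 and 576 fragments, or 122 CPM (113 to 133), in library 2, a relative log2 ratio of 1.30 (1.10 to 1.49). H2-Aa, the alpha chain of an MHC class II molecule, held 32.7 CPM (28.2 to 37.8) in library 1 and 8.71 CPM (6.25 to 11.8) in library 2, a relative log2 ratio of -1.61 (-2.15 to -1.13). The median gene had a log2 ratio of -0.28, or -0.18 with pile-ups masked, and all ratios of genes below are relative to it, so that scaling by fragments near gene starts leaves them as they are.

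Of the fixed gene groups, the MHC class II and co-stimulation list stood apart most clearly, with 9 of 10 genes lower in library 2, 1 higher and 0 neither. The Kupffer markers moved almost as far, with 8 of 9 lower, 1 higher and a list value of -0.81, also below all random lists, so the change was not limited to MHC class II. The MHC class II median lay at -0.84 (-1.01 to -0.65) relative to matched random lists, below all 10000 of them, and at -0.79 with pile-ups masked. H2-Ab1 had a ratio of -1.34 (-1.69 to -1.01) and Cd74 a ratio of -1.27 (-1.5 to -1.05). Cd86 lay at -0.27 (-0.42 to -0.13), but at 0.04 in windows at the gene's fuller end and 0.03 in cells with at least 50% of fragments in peaks. H2-DMa, which helps load peptides onto MHC class II, was the higher member, at 0.25 (0.11 to 0.39). Its window was also open in endothelial-like cells, at 156 and 135 CPM in libraries 1 and 2, against 171 and 168 CPM in Kupffer-like cells. Across H2-Ab1, H2-Aa and H2-Eb1 on chromosome 17, between 34257001 and 34314000 of the files' build GRCm38.p5, 10 bins of 1 kb had 50 or more fragments. Of these 9 were lower in library 2 and 0 were higher, and together they held 1142 fragments in library 1 and 296 in library 2, a relative log2 ratio of -1.38 (-1.57 to -1.19).

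In the heme and iron handling list, 6 of 16 genes were higher in library 2, 3 lower and 7 neither, and the list median lay 0.11 above random lists, at percentile 81.3. With pile-ups masked, 8 were higher, 4 lower and 4 neither, at 0.19 and percentile 95. Values in other settings ranged from 0.02, at percentile 56.1 over gene bodies without flanks, to 0.23, at percentile 94.7 in thinned cells. The highest percentile was 97.34, at 0.22 with fuller gene ends, just inside the central 95%. Fth1 had a ratio of 0.75 (0.54 to 0.95), while Cd163 was lower at -1.33 (-1.60 to -1.07) and the endosomal iron transporter gene Slc11a1 at -0.25 (-0.43 to -0.07), the latter no longer called with pile-ups masked, at -0.14 (-0.33 to 0.04). The higher signal at Hmox1 lay away from the fuller gene end, in the far part of the gene and beyond it, in 7 neighbouring bins of 1 kb on chromosome 8 from 75097001 to 75104000. These held 192 fragments in library 1 and 496 in library 2, a relative log2 ratio of 1.94 (1.70 to 2.19), and the bin at the fuller gene end held 125 and 96 fragments, a ratio of 0.19 (-0.21 to 0.58). The bins were chosen after their values were seen. Of the NRF2 antioxidant targets, 5 of 14 were higher, 1 lower and 8 neither, with a list value of 0.10. Nqo1 was higher at 0.84 (0.36 to 1.33) and the cystine transporter gene Slc7a11 at 0.72 (0.42 to 1.03), or 0.54 and 0.37 with pile-ups masked. Osgin1 was lower at -0.34 (-0.53 to -0.15), and G6pdx had a ratio of -0.29 (-0.60 to 0.00).

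**Figure D4:**
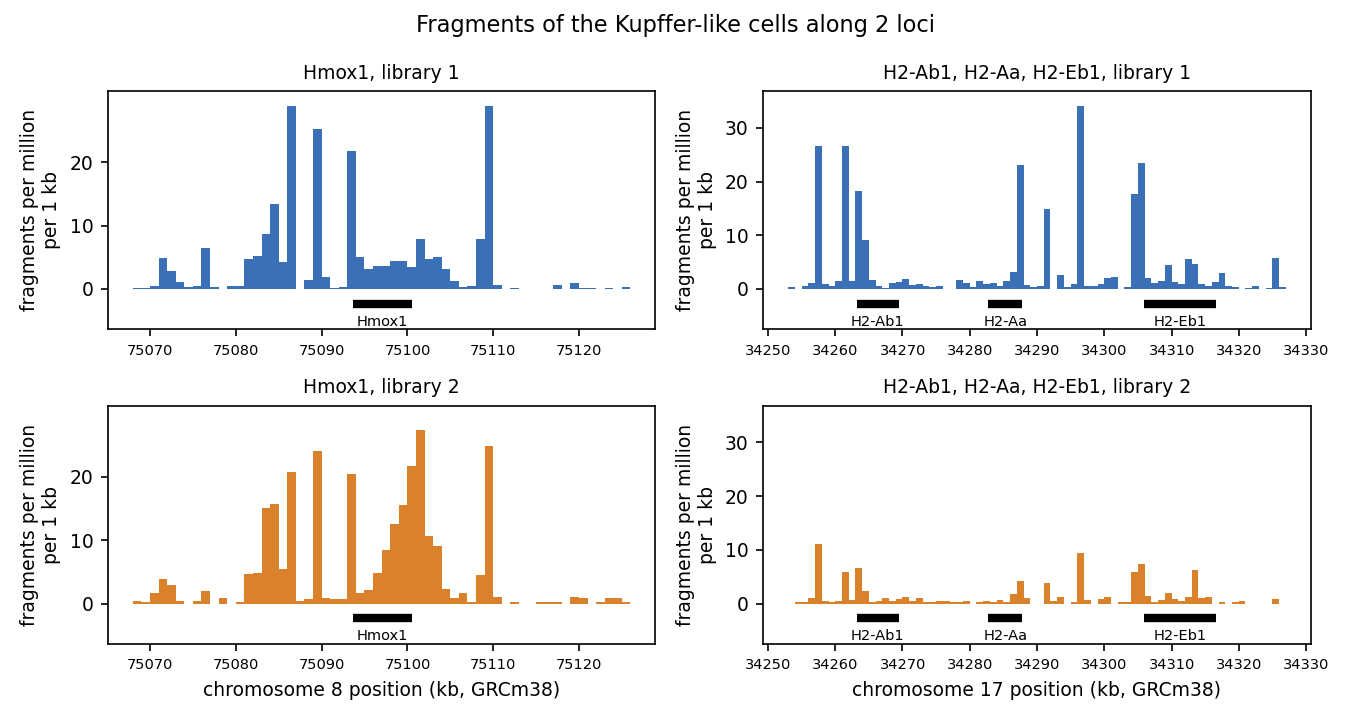
Bars show fragments in CPM of the Kupffer-like cells in bins of 1 kb along Hmox1 on chromosome 8 (left) and H2-Ab1, H2-Aa and H2-Eb1 on chromosome 17 (right), for library 1 (top) and library 2 (bottom), with gene bodies as black bars and positions in kb. The 7 bins from 75097001 to 75104000 held 33.4 CPM in library 1 and 105 in library 2, and 9 of the 10 MHC class II bins with 50 or more fragments were lower in library 2.

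Of the inflammatory response genes, 9 of 16 were lower in library 2, 2 higher and 5 neither, and the list median lay at -0.30 (-0.42 to -0.17) relative to random lists, at percentile 2.02. With pile-ups masked, 6 were lower, 1 higher and 9 neither, with the list at -0.32. Ccl3 and Ccl4, both counted as lower in the main setting, have overlapping windows and share fragments, so they are not independent members. Il6 had a ratio of -0.76 (-1.19 to -0.36) and the lipopolysaccharide co-receptor gene Cd14 a ratio of -0.73 (-1.10 to -0.37). Tnfaip3, which encodes an inhibitor of NF-kappaB signalling, was higher at 0.27 (0.08 to 0.47), and Nos2 at 0.50 (0.05 to 0.95). Nos2 was no longer called with pile-ups masked, at 0.24 (-0.26 to 0.71). The list came inside the central 95% of random lists in 5 of 12 other settings, for example at -0.19 and percentile 7.25 with windows at the fuller gene end. It also came inside against random lists matched on the ratio of Kupffer-like to endothelial-like cells, at percentile 7.84, and without the 20% of cells with most fragments in dendritic, B and monocyte markers, at percentile 3.46, so the inflammatory difference is not firm. Of the anti-inflammatory and alternative activation genes, 6 of 11 were lower, 3 higher and 2 neither, with a list value of -0.31 (-0.44 to -0.16) at percentile 2.69. The value turned to 0.21 at the fuller gene end. Il10 had a ratio of -1.0 (-1.57 to -0.49) and Tgfbi a ratio of -0.75 (-1.0 to -0.50). The 3 higher genes rested on pile-ups, since Ahr moved from 0.95 to 0.30, Pparg from 0.40 to 0.11 and Arg1, the arginase gene of alternatively activated macrophages, from 0.75 to -1.0 once these were masked. In Arg1, 72.7% of the library 2 fragments came from 2 cells. Ahr turned to -0.31 in cells with at least 50% of fragments in peaks, and Arg1 to -0.54 at the fuller gene end.

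Apart from the MHC class II and inflammatory lists, the gene lists lay within the central 95% of random lists. Of the genes in the engulfment and scavenger receptor list, 6 of 12 were lower, 3 higher and 3 neither. The list value was -0.05, which came to 0.05 at the fuller gene end. Stab1 was lower at -1.21 (-1.5 to -0.93) and the complement receptor gene Itgam at -0.77 (-1.07 to -0.48). Gas6 was higher at 0.74 (0.26 to 1.23) and Itgb3 at 1.07 (0.67 to 1.48). Itgb3 was no longer called with pile-ups masked, at 0.26 (-0.22 to 0.72), and turned to -0.22 with each cell thinned to 5000 fragments. In the interferon response list, 3 of 10 genes were lower, 0 higher and 7 neither, with a list value of -0.23, which turned to 0.15 at the fuller gene end and moved to -0.55, at percentile 2.22, over gene bodies without flanks. Ifit3 was lower at -0.99 (-1.48 to -0.54) and Oas1a at -0.84 (-1.62 to -0.15), while Irf7 and Cxcl9 had ratios of 0.20 (-0.14 to 0.53) and 0.57 (-0.29 to 1.43). Of the macrophage identity factors, 5 of 12 were lower, 2 higher and 5 neither, with a list value of -0.12. Spi1 was lower at -0.64 (-0.81 to -0.48) and Id1 at -0.35 (-0.63 to -0.08), the latter no longer called with pile-ups masked, at -0.25 (-0.53 to 0.02), and Rbpj was higher at 0.33 (0.14 to 0.51). In the LXR and lipid handling list, 3 of 9 genes were lower, 1 higher and 5 neither, with a list value of -0.05, which came to 0.13 at the fuller gene end. The cholesterol exporter gene Abcg1 was lower at -0.54 (-0.72 to -0.36) and Apoe at -0.47 (-0.75 to -0.20). Srebf1 had a ratio of 0.16 (-0.05 to 0.38), and Lpcat3 was higher at 0.21 (0.02 to 0.39) but turned to -0.28 over gene bodies without flanks.

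**Figure D5:**
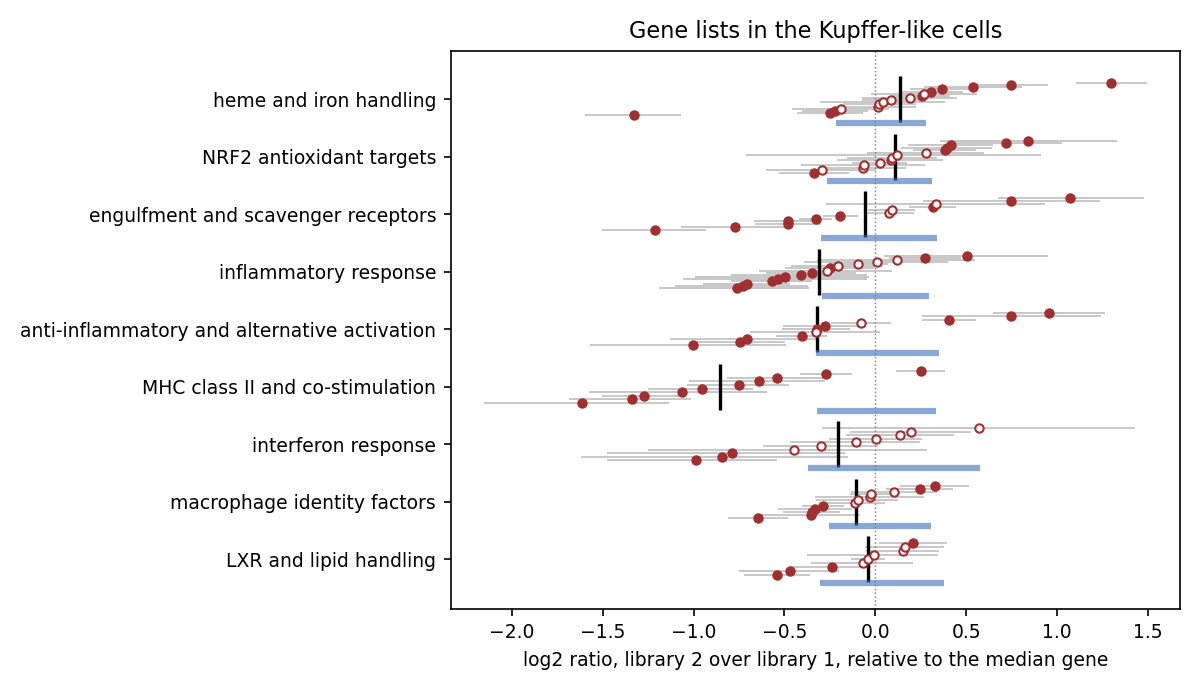
Points show log2 ratios of single genes in Kupffer-like cells, library 2 over library 1, relative to the median gene, filled where the 95% counting interval (grey line) excludes 0. Black ticks mark list medians and blue bars the central 95% of medians of 10000 matched random lists, and the MHC class II and inflammatory ticks lie outside their bars.

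Markers of resident liver macrophages were also less open in library 2. The 1 higher Kupffer marker was Marco, a scavenger receptor gene, at 1.79 (1.54 to 2.04). Timd4 had a ratio of -1.15 (-1.39 to -0.91) and Vsig4 a ratio of -1.05 (-1.33 to -0.78). Marker lists of other cells had values of -0.24 for monocytes (-0.15 with pile-ups masked), -0.30 for neutrophils, -0.38 for conventional dendritic cells, 0.61 for plasmacytoid dendritic cells, 0.30 for endothelial cells, 0.30 for stellate cells or fibroblasts, 0.54 for cholangiocytes, 0.41 for T or NK cells, -0.36 for B cells and -0.07 for erythroid cells. All of these lay within the central 95% of random lists. With pile-ups masked, the endothelial value came to 0.02, the cholangiocyte value to -0.005, the stellate or fibroblast value to 0.15, the neutrophil value to -0.19 and the erythroid value to -0.29, and the B-cell value came to -0.45, just outside the central 95%. The hepatocyte, megakaryocyte and basophil or mast lists had fewer than 3 genes with 50 fragments and were given no median.

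Among single genes, the highest in library 2 rested on few cells. The 10 lowest in library 2 were Calml4, C9, Ms4a6b, Tmem176a, Zdhhc8, Gbp4, Slc9a3r2, 1700008O03Rik, Spata2l and H2-Eb2, at ratios from -2.52 for Calml4 to -1.83 for H2-Eb2. C9 encodes a terminal complement component, Gbp4 an interferon-inducible guanylate-binding protein and H2-Eb2 an MHC class II beta chain. Calml4 held 123 fragments in library 1 and 14 in library 2, and Ms4a6b held 125 and 18, a ratio of -2.19 (-3.03 to -1.51). The 10 highest were 4933402J07Rik, Evx2, Wt1, Pcdha10, Nipal4, Fgf5, Chrm2, Col6a1, Hoxd3 and Lrrtm3, at ratios from 5.05 for 4933402J07Rik to 3.75 for Lrrtm3. In these, 2 cells gave between 56.6% and 85.0% of the library 2 fragments. With pile-ups masked, the 10 highest were Bche, Cntn6, Tmprss15, Cntnap5a, Lrrtm3, Zfp804a, Epha3, Olfm3, Cntnap5b and Plod2, at ratios from 2.88 for Bche to 2.46 for Plod2, with the contactin gene Cntn6 at 2.79 (2.40 to 3.22). In these, 2 cells still gave between 14.3% and 30% of the library 2 fragments. Their levels in library 1 were low, from 3.15 CPM for Bche to 31.5 CPM for Cntnap5a. These genes have long bodies, which were counted whole, for example from 115684737 to 116587323 on chromosome 1 for Cntnap5a. None of them was among the 15 highest at fuller gene ends with pile-ups masked, where fewer genes were tested. Whether gene length or the lower share in peaks of library 2 gave these ratios was not tested.

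Endothelial-like cells were compared between the libraries in the same way, mostly cluster 6 for library 1 and cluster 7 for library 2. Endothelial markers were less open in library 2, with 10 of 12 lower, 0 higher and 2 neither and a list value of -0.49 (-0.62 to -0.37) at percentile 0.09. The median gene had a log2 ratio of -0.18. Fgf23, which encodes a phosphate-regulating hormone, had the highest ratio, with 3 fragments in library 1 and 134 in library 2, a relative log2 ratio of 5.22 (3.86 to 7.74), and 13.4% of the latter came from 2 cells. Gpr139, Ccdc7a, Lrrn2 and Ano5 followed, with 84.8% to 93.7% of library 2 fragments from 2 cells. With pile-ups masked, Fgf23 was followed by Slc2a1, the gene of the glucose transporter GLUT1, at 2.44 (1.84 to 3.14), and by Mei4, Echdc3 and Palmd. The 5 lowest were Jup, Trmt9b, Chst7, S100a13 and Accs, with Jup, which encodes the junction protein plakoglobin, at -2.09 (-2.75 to -1.52). In Chst7, 42.9% of the library 1 fragments came from 2 cells. With pile-ups masked, Wnt2 took the place of Chst7 among the 5 lowest, at -1.79 (-2.25 to -1.37).

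No list of the fixed gene groups stood outside the central 95% of random lists in the endothelial-like cells, but with pile-ups masked the heme and iron list reached percentile 98.0. The heme and iron list had a value of 0.23, with 3 of 14 genes higher, 2 lower and 9 neither, and the MHC class II list 0.17, with 4 genes tested and all 4 neither. Of the NRF2 targets 1 was higher, 1 lower and 11 neither, at 0.11, and of the engulfment list 2, 4 and 5, at -0.14. Inflammatory genes split into 1 higher, 0 lower and 6 neither, at -0.02, and anti-inflammatory genes into 0, 2 and 6, at -0.08. Interferon genes split into 2 higher, 1 lower and 3 neither, at -0.04, identity factors into 1, 4 and 7, at -0.06, and LXR and lipid genes into 2, 2 and 5, at 0.17. The LXR value came to -0.14 with pile-ups masked. Among markers of other cells, 2 lists lay outside the central 95%, namely monocytes at 1.03 and percentile 98.05 (99.1 with pile-ups masked) and conventional dendritic cells at -0.64 and percentile 0.69 (0.6 with pile-ups masked), with 4 genes each. The values were 0.20 for T or NK cells, -0.01 for B cells and 0.14 for erythroid cells, the last of these -0.08 with pile-ups masked. The lower MHC class II signal of the Kupffer-like cells was not tested for a difference from the endothelial-like cells.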

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

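Of the tests in this part, those of deeper sequencing, of faults at fixed loci and of a shift shared by every class were chosen after the results were seen, and the others before.

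Stretches like the pile-ups were also seen in barcodes that were not called cells, which the comparisons do not use. Among barcodes with at least 100 fragments and under 1000 in peaks, dense 20 kb bins held 0.927% of fragments in library 1 and 16.0% in library 2, signals in data outside the main measurement. On that measure, which differs from the pile-up rule above, dense bins of filtered cells held 1.05% and 17.3%. In library 2 the pile-ups were little changed by thinning to the read pairs per fragment of library 1, at 11.7% of fragments, which argues against deeper sequencing. They lay in 97.8% as many different bins as random placement gives. That count cannot decide on faults at fixed loci. A bin high in many cells raises the number expected there, so it tends not to be called a pile-up. Within pile-ups 6.17% of fragments overlapped another of the barcode by 20 bp or more, against 16.6% after random placement, as pieces of free DNA that are each a single molecule would give, so free DNA caught in droplets may be a source. A decondensed stretch of a chromosome of the cell itself would look the same, and library handling and genotype stay open and were not tested, since each has 1 library.

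Kupffer-like and endothelial-like cells of the 2 libraries lay in separate clusters. With pile-ups masked, 97.8% of the nearest Kupffer-like neighbours of Kupffer-like cells came from their own library, against 49.9% with no split. This argues against the masked pile-ups as the sole cause. With only cells with at least 50% of fragments in peaks as well, the share was 98.5%. That value does not decide on the lower share in peaks, because the minimum does not make the libraries equal in it. Before it, the medians of Kupffer-like cells were 73.9% and 53.9%. A shift of the same size in every class cannot be told apart from a shift of these classes, because the excess of own-library neighbours of stellate or fibroblast-like cells was 19.1 percentage points with all fragments and 32.5 with pile-ups masked and cells thinned, and that of Kupffer-like cells 47.4 and 28.4. A biological difference between the genotypes stays open and was not tested.

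The MHC class II and co-stimulation list was lower in the Kupffer-like cells of library 2. Weaker signal over background, which would lower all genes specific to the class, cannot be told apart from a change of this list. The list stayed at -0.72 against random lists matched on level and on the ratio of Kupffer-like to endothelial-like cells, but under the same match the Kupffer markers also stayed low, at -0.60 and percentile 0.025, so the match does not show that all loss of class-specific signal was taken up. Endothelial markers were lower in the endothelial-like cells of library 2 as well, at -0.49 and percentile 0.09, which goes with such a loss. Without the 20% of cells with most fragments in dendritic, B and monocyte markers the list lay at -0.92, which argues against such cells in the pool of library 1. What also stays open is library handling and the genotypes of the mice, which were not tested and cannot be told apart with 1 library each.

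Barcodes not called cells with at least 1000 fragments in peaks numbered 83 in library 1 and 107 in library 2, which is again a signal in data that the comparisons do not use. The marker values of monocytes had different signs in the 2 classes, at -0.24 in Kupffer-like and 1.03 in endothelial-like cells, as had those of endothelial cells, at 0.30 and -0.49, and neither difference was tested. Both Kupffer-like values lay within the central 95% of random lists, at percentiles 12.4 and 93.0, and with pile-ups masked they were -0.15 and 0.02, so no change in the Kupffer-like cells is shown. Both endothelial-like values lay outside the central 95%, at percentiles 98.05 and 0.09. These were 2 of the 15 lists measured in both classes.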

How the results depend on the processing

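The lower MHC class II list in Kupffer-like cells kept its direction and stayed outside the central 95% of random lists in all 13 settings, from -0.91 to -0.72, and the inflammatory list kept its direction, from -0.34 to -0.19, but came inside the central 95% in 5 of the 12 other settings, when matched on the ratio between the classes (percentile 7.84) and without cells high in markers of other cells (percentile 3.46). The heme and iron list ranged from 0.021 without flanks to 0.23 in thinned cells, and its highest percentile was 97.34, with fuller gene ends. Between classes, the heme and iron list of library 1 ranged from 0.21 to 0.72, with a lowest percentile of 94.7. Of the alternatives named below, fuller gene ends, masked pile-ups, the 50% minimum in peaks, bodies without flanks and matching on window length were chosen after seeing the data. The Kupffer-like share was 46.6% in library 1 with no cell filter, and in library 2 it was 52.5% with 20 kb bins, 33.3% at Leiden resolution 1 and 40.8% without cells marked by scrublet. The unnamed shares came to 9.03% and 17.6% with 20 kb bins, 8.87% and 12.4% without overlap-marked cells, and 22.9% in library 1 with no cell filter. The lists outside the central 95% came to 1 in place of 2 with fuller gene ends, thinned cells, the 50% minimum in peaks and matching on window length, and to 3 without flanks, where the anti-inflammatory (percentile 1.99) and interferon lists (-0.55, percentile 2.22) entered and the inflammatory list (percentile 6.2) left. The median gene moved to -0.44 with fuller gene ends, to 0.0035 with scaling near transcription start sites and to -0.18 with masked pile-ups or the 50% minimum. With fuller gene ends, the anti-inflammatory list turned to 0.21, the interferon list to 0.15, the LXR list from -0.053 to 0.13 and the engulfment list from -0.049 to 0.047, Arg1 to -0.54 and Cd86 to 0.038, and between classes the engulfment list of library 1 turned to -0.034 and the interferon list of library 2 to 0.17. Arg1 turned to -1.0 with masked pile-ups, where the fragments of a few cells are removed by construction. Itgb3 turned to -0.22 in thinned cells, Ahr to -0.31 and Cd86 to 0.027 with the 50% minimum, and Lpcat3 to -0.28 without flanks. For the other changes the cause was not tested. Of the values of named genes 610 were the same, 61 moved and 7 reversed. Scaling by fragments near transcription start sites leaves these values the same by construction, so that part of the 610 is no sign of stability. Of the values for gene lists in Kupffer-like cells 117 were the same, 12 moved and 3 reversed. Besides list values, these include the number of lists outside the central 95% and the median gene. Of the values for lists between classes 202 were the same, 16 moved and 2 reversed, again with the number of lists outside included. Of class shares 34 were the same and 16 moved, and all 4 numbers of cells stayed within 1.5 times those reported. No paired analysis was possible because each group has 1 library. The 3 motif alternatives and the windows at transcription start sites were not run. A change of 1.5 times was called in 74% of simulated genes, so changes of that size can be missed.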

Other observations

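All comparisons in this part were chosen after the data were seen. Windows of 1 kb on each side of the fuller gene end, with pile-ups masked, gave the changes in this paragraph. Mgst1, a microsomal glutathione transferase gene, held 72 fragments in Kupffer-like cells of library 1 and 175 of library 2, a relative log2 ratio of 2.02 (1.62 to 2.44). Fzd1, a Wnt receptor gene, had a ratio of 1.86 (1.40 to 2.36), Bhlhe41 a ratio of 1.40 (0.91 to 1.91) and Hpgds, the hematopoietic prostaglandin D synthase gene, a ratio of 1.37 (0.95 to 1.79). Lower in library 2 were Scimp, an adaptor of MHC class II signalling, at -2.84 (-4.17 to -1.88), Cd74 at -2.64 (-3.36 to -2.05), the pyrin gene Mefv at -2.20 (-3.16 to -1.44) and Il18 at -1.74 (-2.40 to -1.18). Lars2 was higher in both classes, at 1.88 in Kupffer-like and 2.15 in endothelial-like cells, and Tmem176a was lower in Kupffer-like cells at -2.22 and higher in endothelial-like cells at 2.35.

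The MHC class II list was lower in cluster 1 of library 2 than in each Kupffer-like cluster of library 1, at -0.82 against cluster 3, -1.08 against cluster 5 and -0.83 against cluster 9. Within library 1, cells of clusters 3, 5 and 9 differed in depth, with medians of 16599.5, 7703.5 and 28223 fragments, and were not thinned to equal depth. There the anti-inflammatory list median was lower in cluster 5 than in cluster 3, at -0.32 (-0.51 to -0.13) and percentile 0.15 of random lists, with 1 gene higher, 1 lower and 8 neither, and the MHC class II median was higher, at 0.23 (0.05 to 0.45) and percentile 97.8, with 2 higher, 0 lower and 8 neither. The NRF2 median was lower in cluster 9 than in cluster 3, at -0.19 (-0.34 to -0.04) and percentile 0.465, with 0 higher, 3 lower and 10 neither. Whether depth gave these differences was not tested. These clusters were made from the same fragments, so such differences are not independent of how the clusters were formed.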
